A study of Arabidopsis thaliana with 9 samples.

How the data were processed

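Leaf RNA from 3 groups of 3 samples was hybridised to 9 ATH1 arrays. Per the labels' protocols, each sample was pooled from 5 plants grown 28 to a tray at 23 °C by day and 19 °C by night with 12 h of light, and biotin-labelled cRNA was prepared from 3 µg of total RNA. The labels give separate samples, so p-values measure the spread between these pooled samples. Per the submitters' processing notes, the deposited log2 values came from RMA, which summarises the probes of a set; its version and background model are not given in the sources used here. The columns' quantiles differ slightly. No array of another sample was in the table.

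The table held 22810 probe sets. The 64 control probe sets were left out of the tests and 22746 were tested. The probe annotation gave 1 gene name to 13513 probe sets, several to 503 and none to 8730 of those tested. A gene was represented by the probe set naming it alone with the highest mean over 9 arrays, which gave 13355 genes, 1557 of them with a symbol rather than a locus code. Of the singly named probe sets, 13436 matched a locus of the TAIR10.1 reference, which was used for names and for the order of neighbouring genes only.

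Group differences were tested with limma 3.58.1 in R 4.3.3, with all groups in 1 fit, no block and Benjamini-Hochberg adjustment over all tested probe sets within each comparison, at an adjusted p of 0.05. Counts were taken over the 13355 genes. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over lists of at least 3 measured members. Of 318 members written for 23 lists before the data were examined, 30 were measured under their own name, 284 had no named probe set and 4 were dropped for another name; 3 of these lists could be tested and 7 had no member. Another 24 lists, with 353 measured members, were written from the names in the probe annotation before any gene's values were seen. The text names the members of the biotin lists, the 10 largest rises and 10 largest falls past the threshold whose replicates do not overlap, and leading members of the gene lists: the 4 with the largest change in bio4-1 minus wild type. This rule was also applied to arrays 2 and 3. The rule fixed beforehand asked for such members of every list; they are given only for lists past the threshold on all 9 arrays, in the comparisons they passed in, a limit set after the list results were seen, to keep the text short.

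On simulated arrays with independent noise, 52 of 100 genes changed 2-fold and 77 of 100 changed 4-fold between bio4-1 and wild type were called on 9 arrays, over 13355 genes. On arrays 2 and 3 these were 71 and 96. The simulation holds no batch of arrays. Alternatives were a replicate block, other normalizations, filters on dim probe sets, other variance models, array weights, 2-group fits, other thresholds, other choices of probe sets and leaving out each array. Arrays 2 and 3 alone, and the arrays numbered 1 against the others as a block, were added after the data were seen. A pseudocount does not apply to log2 values. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.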

Results

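Transcript levels were measured in rosette leaves of Arabidopsis thaliana ecotype Col-0 on Affymetrix ATH1 arrays, a 1-colour array in which a set of short probes reports each transcript. The 3 groups were wild type plants, the bio4-1 mutant, and bio4-1 watered with 200 µM D-biotin. In the mutant, T-DNA interrupts the 5' UTR of BIO4, a gene of the synthesis of biotin, the cofactor of carboxylases. Each group had 3 arrays, and each RNA was pooled from 5 plants of 5 weeks. The deposited values were log2 expression summaries, with array medians from 5.95 to 6.07, and the number of arrays limited the precision of every comparison. The level of BIO4 itself was not analysed here, because no probe set was paired with that gene by the annotation used.

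The arrays numbered 1 stood apart from the others in all 3 groups. Pairs of arrays that included exactly 1 of these 3 correlated at 0.95 to 0.972 across probe sets, whereas the 15 pairs among arrays 2 and 3 correlated at 0.987 to 0.997. Wild type array 1 and biotin-watered array 1 lay together on the first principal component at −69.02 and −69.04, and bio4-1 array 1 lay apart on the second at 77.2. With the arrays numbered 1 set against arrays 2 and 3 in the limma fit, 2885 of 13355 genes differed. Such a block takes the shift as the same in all 3 groups, which the place of bio4-1 array 1 goes against. On the arrays numbered 1, the actin control probe sets had a 3' minus 5' difference of 3.67 to 4.13 on the log2 scale, against 2.27 to 2.76 on the other 6; for ubiquitin it was 1.52 to 1.73, against 1.48 to 1.72. Each comparison is therefore given on all 9 arrays, as fixed before the data were examined, and also on arrays 2 and 3 alone, an alternative chosen after the data were seen. Differences between the single arrays numbered 1 carry no test.

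**Figure D1:**
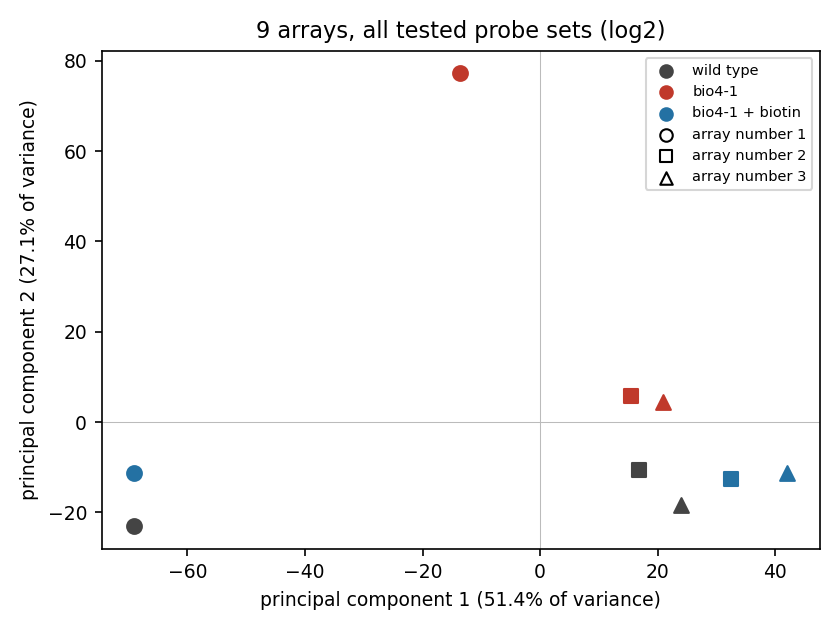
First and second principal components of the 9 arrays over all tested probe sets, in log2 units, with colour for the group and marker shape for the array number. Array 1 of wild type (−69.02) and of biotin-watered bio4-1 (−69.04) lie far left, and array 1 of bio4-1 lies at 77.2 on the second component.

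The first comparison asked which transcripts differ between leaves of water-grown bio4-1 and wild type. MSRB9, a methionine sulfoxide reductase encoded at AT4G21850 on chromosome 4, had a mean log2 level of 5.04 ± 0.57 (SD, n = 3) in wild type and 14.04 ± 0.08 (SD, n = 3) in bio4-1, a difference of 9.0 ± 0.26 (SE; limma adjusted p = 1.3e-05). This level lay within 0.58 of the highest value of each mutant array, and was itself the highest on biotin-watered array 1, so the size of the difference is limited by the top of the array range. AT4G12500, of a lipid transfer protein family, rose by 3.54 ± 0.37 (SE) with a limma adjusted p of 0.0381. AT2G17740 rose by 2.58 ± 0.23 (adjusted p = 0.0217), AT3G60580 by 1.13 ± 0.10 (adjusted p = 0.0217) and AT2G15760 by 0.83 ± 0.08 (adjusted p = 0.0364). These 5 genes were all of those past the limma threshold on 9 arrays, and 882 genes had an unadjusted p under 0.05, against 667.75 expected by chance. Without wild type array 1, 2 or 3, or bio4-1 array 1, 2 or 3, or biotin-watered array 2, 1 gene was called, and 2 were called without biotin-watered array 3. Of the 5 genes, only MSRB9 kept its call under every alternative.

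On arrays 2 and 3, 254 genes rose and 199 fell in bio4-1, or 265 and 319 after median centring. Leaving out 1 of these 6 arrays at a time left 7 to 107 genes. The mean 3' minus 5' difference of the actin, GAPDH and ubiquitin controls was 1.39 and 1.33 on bio4-1 arrays 2 and 3. That was above the 1.29 and 1.17 of wild type, and its part in these changes was not tested. With the difference between the arrays numbered 1 and the others as a block in the fit on all 9 arrays, 26 rose and 7 fell. The 10 largest rises on arrays 2 and 3 were those of MSRB9, AT4G12490, AT4G12500, CCOAMT, NRT2.5, EXO, AT2G17740, AT5G38710, AT3G18250 and CHI. AT4G12490 rose by 4.45 ± 0.29 (SE), CCOAMT, an O-methyltransferase acting on caffeoyl-CoA, by 3.18 ± 0.28, the nitrate transporter gene NRT2.5 by 3.00 ± 0.44, and CHI, here a putative chitinase gene, by 2.34 ± 0.48, with limma adjusted p of 0.0432 for CHI and lower values for the other 3. On the arrays numbered 1, the bio4-1 array was above the wild type array by 6.73 for AT4G12490, 4.96 for CCOAMT and 6.68 for CHI, but by 0.20 for NRT2.5. The 10 largest falls were those of AT1G62290, AT1G20070, AT1G77960, AT1G49500, AT1G62510, THI2.2, AT5G05960, IAA29, AT5G03230 and AT3G08030. AT1G62290 fell by 2.57 ± 0.18 and IAA29, an auxin-inducible gene, fell by 1.75 ± 0.20, with differences of −2.35 and −1.98 on the arrays numbered 1. THI2.2, a thionin gene, fell by 2.00 ± 0.30 on arrays 2 and 3 but was 1.09 higher in bio4-1 on the arrays numbered 1, and AT1G49500 and AT3G08030 were 1.99 and 3.53 higher there. Of the 254 genes raised on arrays 2 and 3, 217 (85.4%) were also higher in bio4-1 on the arrays numbered 1, against 42.7% of uncalled genes with a positive difference. Of the 199 lowered genes, 111 (55.8%) were lower there, against 57.5% of uncalled genes.

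Over all 9 arrays, the list of 24 immune receptors, regulators and defence proteins had a median difference of 0.74, and the 3 measured members of the salicylic acid list had one of 1.93 (camera adjusted p of 8e-12 and 4.67e-05). The adjusted p was 0.329 for both lists with an estimated correlation. The planned list of ethylene and jasmonate defence, with 2 measured members and so not tested, had a median of −1.13, with 0.05 on arrays 2 and 3 and −3.49 on the arrays numbered 1. No member of the 24 passed over all genes, and 10 rose when adjusted over the list alone; all 3 of the salicylic acid list rose when adjusted over the list alone. The glutaredoxin gene GRX480 was 2.18 higher, the osmotin gene OSM34 2.01, the regulator gene WRKY53 1.93 and the defensin-like gene PDF1.4 1.74 higher over all arrays, with limma adjusted p of 0.270, 0.323, 0.546 and 0.089. SAG101, of the salicylic acid list, was 0.86 higher (adjusted p = 0.498), and 0.53 higher with 1 array left out. GRX480 and WRKY53 belong to both the immune and the salicylic acid list, so the lists are not separate evidence. On arrays 2 and 3, 6 of the 24 were called, all upward, and GRX480, OSM34 and PDF1.4 rose by 1.58, 1.27 and 1.66; WRKY53 was 0.73 higher there with an adjusted p of 0.0795. The list medians were 0.52 and 0.73 on arrays 2 and 3, with camera adjusted p of 5.81e-07 and 0.00122, and 0.504 and 0.754 with an estimated correlation. The medians on the arrays numbered 1 were 1.2 and 3.39. With the arrays numbered 1 against the others as a block, the list medians were 0.74 and 1.93 with adjusted p of 1.2e-10 and 0.00111, and with array weights they were 0.43 and 0.73.

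In the same comparison, the 3 measured members of the planned abscisic acid, drought and cold list had a median difference of −0.91 (camera adjusted p = 0.0378) and the 19 of the list written later −0.29 (adjusted p = 0.0346). With an estimated correlation the adjusted p was 0.937 for both. No member passed over all genes, and 1 of each list fell when adjusted over the list alone. On arrays 2 and 3 the medians were −0.17 (adjusted p = 0.506) and −0.04 (0.396), and on the arrays numbered 1 they were −2.39 and −1.24. Without bio4-1 array 1 they were −0.29 (0.163) and −0.20 (0.204), and in all, leaving out a single array ended the call of the planned list in 7 of 9 cases and of the other in 4. With the arrays numbered 1 against the others as a block, the adjusted p was 0.117 and 0.0242. The planned list also lost its call with quantile normalization (0.0561), both lists lost it with median centring (0.0701 and 0.0775), and array weights gave medians of −0.24 (0.526) and −0.07 (0.277). The median of the 19 genes also moved to −0.18 (0.229), −0.65 (0.00079) and −0.48 (0.0810) without wild type array 1, bio4-1 array 2 or bio4-1 array 3, and to −0.51 with either filter on dim probe sets. COR15A, a chloroplast cold-response gene, had 12.19 ± 0.14 (SD, n = 3) in wild type and 10.73 ± 0.70 in bio4-1, a difference of −1.46 with a limma adjusted p of 0.277. This gene belongs to both lists, so the lists are not separate evidence. COR15B and COR47 differed by −1.07 and −0.91, the linker histone gene HIS1-3 by −1.28, the dehydrin gene LTI30 by −0.51 and the ubiquitin ligase gene PUB19 by −1.62, with limma adjusted p from 0.774 to 0.956. With 1 array left out, the smallest differences were −0.42 for COR15B, −0.29 for COR47, −0.25 for HIS1-3 and −1.08 for PUB19, and LTI30 reached 0.15. On arrays 2 and 3, COR15A, COR15B and PUB19 fell (−1.12, −0.76 and −1.36), and 1 of the 19 genes rose, whereas LTI30 and HIS1-3 differed by 0.64 and 0.14.

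MCCA and MCCB, the subunits of the biotin-dependent 3-methylcrotonyl-CoA carboxylase, were the only genes of the biotin lists with a named probe set. MCCA differed by 0.06 ± 0.21 (SE) and MCCB by −0.30 ± 0.10 between bio4-1 and wild type on all 9 arrays, with limma adjusted p of 0.992 and 0.545.

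**Figure D2:**
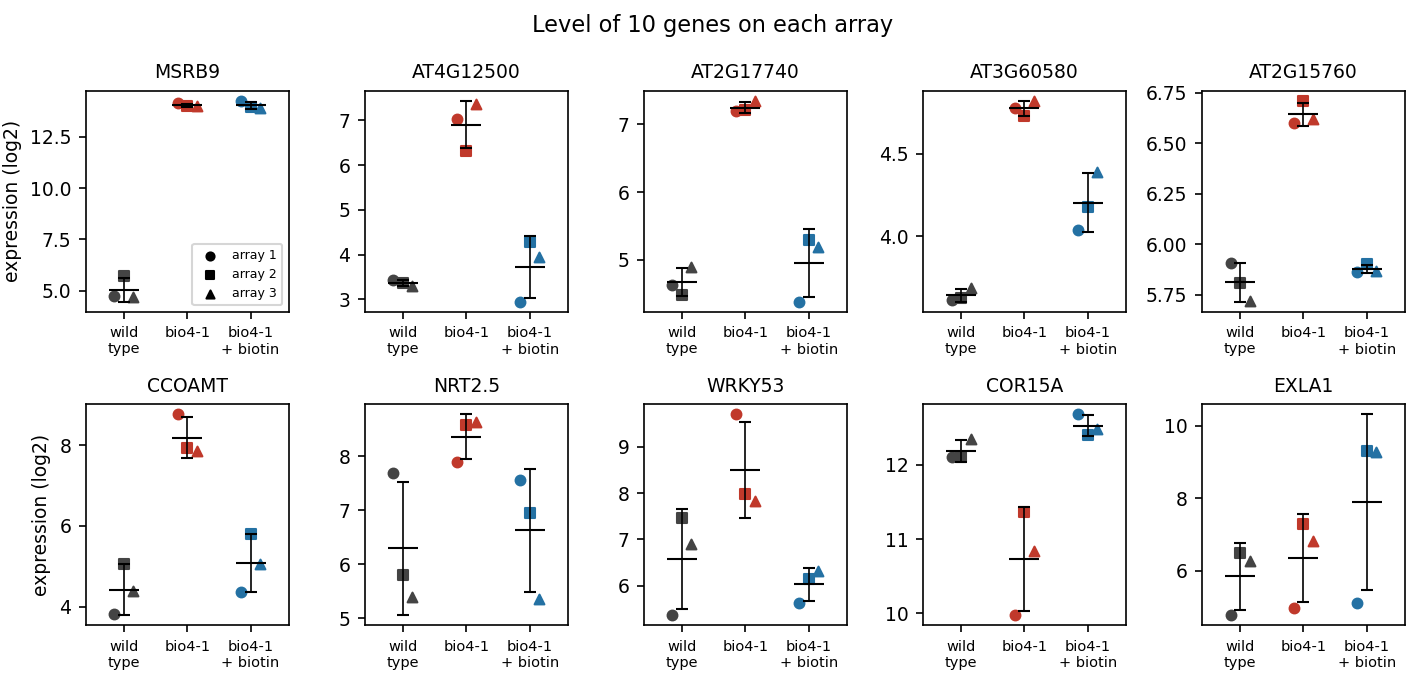
Log2 level of 10 genes on each array, by group, with marker shape for the array number; the black bar and whiskers are the mean and SD of 3 arrays. MSRB9 lies near 14 on all 6 mutant arrays, and AT4G12500 has a mean of 6.90 in bio4-1, 3.36 in wild type and 3.73 in biotin-watered bio4-1.

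The second comparison set biotin-watered bio4-1 against water-grown bio4-1. No biotin-watered wild type was among the samples, so an effect of biotin watering on any plant cannot be told from one particular to the mutant. No gene passed the limma threshold on all 9 arrays, and 550 had an unadjusted p under 0.05, fewer than the 667.75 expected by chance. The lack of calls does not show a lack of change. Over all arrays AT4G12500 differed by −3.18, AT2G17740 by −2.30 and CCOAMT by −3.12, with adjusted p of 0.184, 0.184 and 0.190. MSRB9 differed by −0.01 ± 0.26 (SE), with 14.03 ± 0.18 (SD, n = 3) in biotin-watered plants, a level at which a partial fall could be hidden by the top of the array range. Without biotin-watered array 1, 1 gene was called, and it fell.

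With biotin, 165 genes rose and 201 fell on arrays 2 and 3, or 316 and 209 after median centring. Leaving out 1 of these 6 arrays at a time left 0 to 56 genes. The mean 3' minus 5' difference of the controls was 1.28 and 1.17 on biotin-watered arrays 2 and 3. That was below the 1.39 and 1.33 of water-grown bio4-1, and its part in these changes was not tested. With the arrays numbered 1 against the others as a block, 1 rose and 6 fell. The largest falls were those of AT4G12500 (−2.72 ± 0.30, SE), CCOAMT (−2.48 ± 0.28), NRT2.5 (−2.44 ± 0.44), AT4G12490, AT2G15020, AT2G17740, AT1G51890, AT3G13950, AT1G26390 and WRKY53, which fell by 1.68 ± 0.18 with a limma adjusted p of 0.00873. On the arrays numbered 1, 8 of these differed by −2.81 to −6.83, whereas NRT2.5 differed by −0.33 and AT2G15020 by 0.46. The largest rises were those of XTH33 (2.40 ± 0.29), AT4G16563 (2.27 ± 0.21), EXLA1 (2.24 ± 0.16), AT1G62290, AT5G05960, AT1G11380, AT3G59350, AT3G28310, ULT1 and BZIP61. XTH33 and EXLA1 encode a xyloglucan hydrolase and an expansin-like protein of the cell wall, and were 0.06 and 0.12 higher with biotin on the arrays numbered 1. AT1G62290, which rose by 2.06 on arrays 2 and 3, was 1.63 higher on the arrays numbered 1, and BZIP61 differed by −1.58 there. Of the 201 lowered genes 57.2% were lower on the arrays numbered 1, against 38.2% of uncalled genes; of the 165 raised genes 46.7% were higher, against 54.4%.

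The same lists, some of which share members, were tested for the change with biotin. On all 9 arrays the medians were −0.42 for the 24 immune genes (camera adjusted p = 3.67e-12) and −2.32 for the salicylic acid list (4.5e-05), with an adjusted p of 0.222 for both with an estimated correlation. When adjusted over the list alone, 6 and 2 members fell. The medians on arrays 2 and 3 were −0.09 (adjusted p = 0.00727, or 0.464 with an estimated correlation) and −1.54 (0.0118, or 0.596 with an estimated correlation), and 6 of the 24 immune genes fell. The salicylic acid list had 2 of 3 members lowered there. On the arrays numbered 1 the medians were −1.39 and −3.87. Over all arrays GRX480 differed by −2.32, OSM34 by −1.94, WRKY53 by −2.48, PDF1.4 by −1.53 and SAG101 by −0.35 (−0.03 with 1 array left out), with limma adjusted p of 0.547, 0.772, 0.823, 0.184 and 1. GRX480, OSM34 and PDF1.4 fell on arrays 2 and 3 (−1.54, −1.19 and −1.37), where SAG101 differed by 0.04. The immune median was −0.70 without biotin-watered array 3, and array weights gave −0.16 and −1.42. The 2 measured members of the planned ethylene and jasmonate defence list, which was not tested, had a median of −0.12 on all 9 arrays, 0.85 on arrays 2 and 3 and −2.05 on the arrays numbered 1.

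The planned abscisic acid, drought and cold list had a median of 1.70 (camera adjusted p = 8.56e-05, or 0.232 with an estimated correlation), and all 3 members rose when adjusted over the list alone. Its median was 1.05 (0.00335, or 0.596 with an estimated correlation) on arrays 2 and 3, 2.70 on the arrays numbered 1 and 1.03 without bio4-1 array 1. The 19 cold, drought and abscisic acid genes had a median of 0.55 (0.00665, or 0.561 with an estimated correlation). The list lost its call on arrays 2 and 3, with 0.11 (0.464), where 3 genes rose and none fell, COR15A (1.34) and COR15B (0.92) among them, and had 1.08 on the arrays numbered 1; without biotin-watered array 1 the median was 0.02 (0.365), and with array weights 0.08 (0.534). Over all arrays COR15A was 1.79 higher with biotin, COR15B 1.25, COR47 1.26, LTI30 1.70, HIS1-3 0.91 and PUB19 0.55 higher, with limma adjusted p of 0.395 for COR15A and 1 for the others. With 1 array left out, the lowest values were 0.60 for COR15B, 0.64 for COR47, 1.03 for LTI30, −0.16 for HIS1-3 and −0.96 for PUB19.

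The 19 expansins and xyloglucan hydrolases had a median of 0.19 (camera adjusted p = 0.000598, or 0.432 with an estimated correlation). Its value on arrays 2 and 3 was 0.29 (1.84e-06, or 0.389 with an estimated correlation), where 4 genes rose, and on the arrays numbered 1 it was 0.13. By fry the list passed on arrays 2 and 3 (adjusted p = 0.0258); on all 9 arrays no list passed by fry. EXLB1, EXPB3, EXPA4 and XTH16 differed by 0.91, 0.64, 0.36 and 0.05 over all arrays, each with a limma adjusted p of 1, and with 1 array left out they reached 0.60, 0.38, 0.08 and −0.52. For the list, the filter at the 30th percentile gave a median of 0.48, array weights gave 0.31, and the filter at log2 6 ended the call (0.124). The 31 UDP-glycosyltransferases had a median of −0.04 (0.0404, or 0.222 with an estimated correlation), with −0.04 (0.0228, or 0.464 with an estimated correlation) on arrays 2 and 3 and 0.02 on the arrays numbered 1; 2 genes fell on arrays 2 and 3. This list lost its call without wild type array 2 (0.0522), bio4-1 array 1 (0.205) or biotin-watered array 2 or 3 (0.0700 and 0.161), with array weights (median −0.10; 0.0752) and with either filter on dim probe sets (0.200 and 0.124), and its median was −0.11 without biotin-watered array 1. Over all arrays UGT71B6 differed by −1.22, UGT73D1 by −1.10, UGT72B3 by 0.40 and UGT76E11 by −0.04, with limma adjusted p of 0.628 for UGT71B6 and 1 for the others; with 1 array left out UGT73D1, UGT72B3 and UGT76E11 reached 0.05, −0.25 and 0.16. No member of these 6 lists passed over all genes on 9 arrays. With the arrays numbered 1 against the others as a block the lists kept adjusted p of 4.53e-10, 0.000988, 0.00122, 0.00342, 0.000373 and 0.0419, in the order named. MCCA and MCCB differed by 0.20 and 0.22 with biotin (limma adjusted p = 1 for both), and MCCA by 0.03 with 1 array left out.

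**Figure D3:**
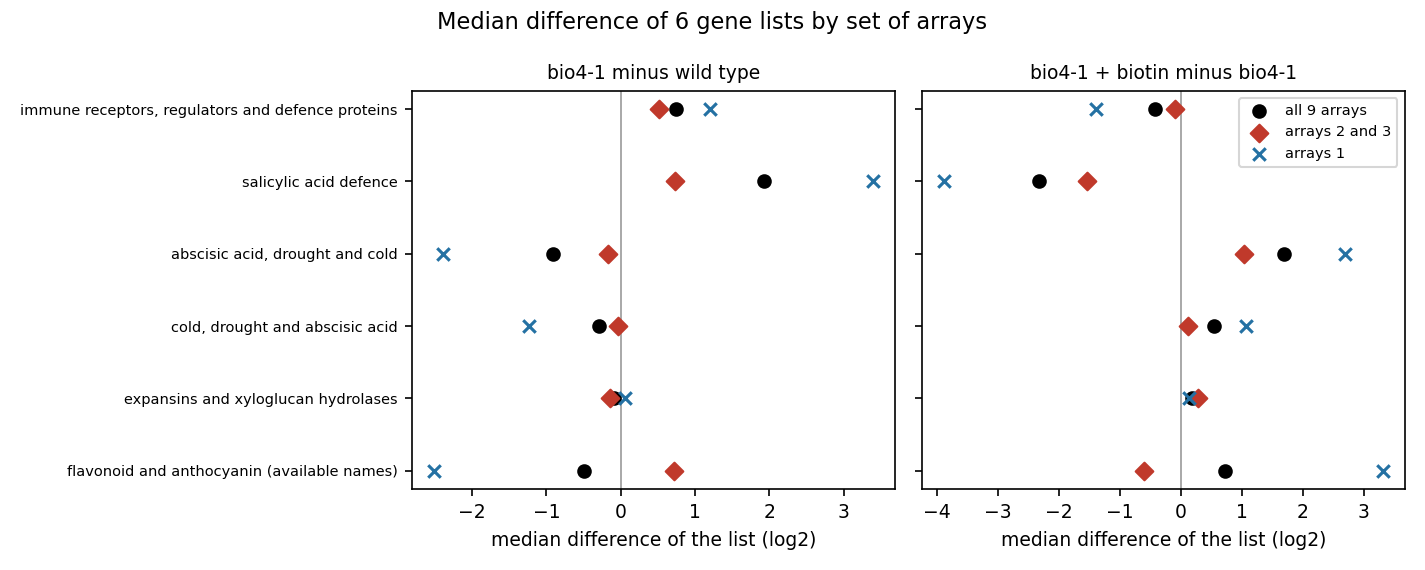
Median log2 difference of 6 gene lists in 2 comparisons, from all 9 arrays (circles), arrays 2 and 3 (diamonds) and the single arrays numbered 1 (crosses). The immune list has medians of 0.74, 0.52 and 1.2 in bio4-1 minus wild type; the flavonoid and anthocyanin list has −0.61 on arrays 2 and 3 and 3.32 on the arrays numbered 1 in biotin-watered minus water-grown bio4-1.

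Biotin-watered bio4-1 was also set against water-grown wild type, so genotype and watering both differed. MSRB9 was the 1 gene past the limma threshold on all 9 arrays, 8.99 ± 0.26 (SE) higher. In all, 308 genes had an unadjusted p under 0.05, fewer than the 667.75 expected by chance. Without biotin-watered array 1, 3 genes were called. None of the 27 gene lists tested passed, and the lowest camera adjusted p was 0.177.

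Of the genes, 279 were higher and 294 lower in biotin-watered bio4-1 than in wild type on arrays 2 and 3, and the block on all 9 arrays left 1 gene. Leaving out 1 of these 6 arrays at a time left 2 to 226 genes. The largest rises were those of MSRB9 (8.72 ± 0.28), EXO (4.2 ± 0.25), XTH33 (3.1 ± 0.29), AT1G50040 (3.04 ± 0.32), EXLA1, AT4G16563, AT5G05600, AT1G11380, AT3G19680 and AT5G25240. EXO, a cell expansion gene, was 0.52 higher on the arrays numbered 1. The largest falls were those of AT2G15020 (−3.35 ± 0.23), the transcription factor gene ORA47 (−2.60 ± 0.25), AT1G60590, AT1G64500, AT1G20070, AT5G03230, PUB19, AT4G24700, AT5G01790 and AT1G76240, and ORA47 was 0.15 higher on the arrays numbered 1. Of the 573 genes, 320 (55.8%) had the same direction there, against 51.9% of uncalled genes.

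On all 9 arrays no gene was changed in bio4-1 and changed back by biotin, and 1 gene, MSRB9, was changed in bio4-1 and still changed with biotin. Without a biotin-watered wild type, a change back cannot be told from a response that wild type would also show. On arrays 2 and 3, 115 genes were changed back, 73 of them raised and 42 lowered in bio4-1, and 178 were still changed, 95 raised and 83 lowered; leaving out 1 of these 6 arrays at a time left 0 to 13 and 1 to 28. Independent lists of these sizes would share 3.82 and 2.46, and 5.31 and 4.38 genes. Simulated arrays with no effect gave 0 in each of 50 draws. Few genes are called without an effect, so this says nothing about the overlap of lists of these sizes. The compared pairs share arrays, so part of the excess over independent lists may come from these. The correlation of the first and second comparisons on arrays 2 and 3 was −0.447, against −0.499 in simulations without effect. There it was no stronger than that given by the shared bio4-1 arrays. Genes still changed with biotin weaken this correlation, so it cannot decide whether other genes change back. On all 9 arrays it was stronger, −0.749 against −0.503, but the simulations hold no batch of arrays. Between the first comparison and that of biotin-watered bio4-1 with wild type, the correlation on arrays 2 and 3 was 0.608 against 0.501. On all 9 arrays that correlation was 0.554 against 0.497. On arrays 2 and 3 the covariances were −0.0352 against −0.0112 and 0.0540 against 0.0112. On all 9 arrays they were −0.0733 against −0.0433 and 0.0432 against 0.0426. Covariances grow with the variance of the values alone.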

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

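Of the tests in this part, those of the control probe sets, of MSRB9 and its neighbours, and of direction on the arrays numbered 1 were chosen after the results were seen; those of the clock and light list and of other splits were fixed before. Groups of 3 arrays were not tested for samples far from the others. The results named first come from control probe sets that the tests left out, at levels above those of wild type, and from probe sets without a gene name, which were tested but not counted among the genes.

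In all 5 pairs of control probe sets examined, the highest 3' minus 5' difference of the mutant arrays was above that of wild type. More mutant than wild type arrays entered, so a higher mutant maximum is likely without any difference between groups. The 3' minus 5' difference reached 4.13 for actin, 2.61 for GAPDH and 1.73 for ubiquitin on biotin-watered array 1, against at most 3.67, 1.55 and 1.56 in wild type. It reached 2.44 for the second actin pair and 0.52 for the second GAPDH pair on bio4-1 array 1, against at most 1.68 and 0.01 in wild type. Among probe sets without a gene name, 1 differed by −1.69 between bio4-1 and wild type (limma adjusted p = 0.0217) and another by 1.09 (adjusted p = 0.0217).

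The arrays numbered 1 stood apart in every group. No tested explanation was excluded. A hybridisation or labelling batch stays open, with 7 of 18 hybridisation control probe sets higher on each of these 3 arrays than on any other: 7 of 8 for bioD and cre, and 0 of 10 for bioB and bioC. As hybridisation controls, these do not test the labelling step. RNA shortened at the 5' end also stays open, with a larger 3' minus 5' difference in 3 of 5 control pairs. Values overlapped in ubiquitin and in the second GAPDH pair. A second ubiquitin pair was left out of these tests, and its values overlapped as well. The bacterial dap, lys, phe and thr control probe sets were not part of these tests. Their 3' minus 5' difference was larger on each array numbered 1 than on any other, except in the second dap pair, which overlapped. Those controls are not leaf RNA, so the larger difference in the leaf controls does not by itself point to shortened leaf RNA. Another time of day at harvest stays open as well, since the mean absolute difference of 8 clock and light genes was 1.087, at percentile 100 of random lists. The array number had no biological meaning in the labels, so no other biological explanation was tested.

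MSRB9 was raised on all 6 mutant arrays. A rise of most of its neighbours near the size of its own is argued against by the median difference of 0.061 over the 10 nearest represented genes. This median lay close to the 95th percentile of 0.068 over other windows, so a small shared rise stays open. A median also cannot show a rise of only a few adjacent genes. A response to low biotin stays open: the difference of −0.012 between biotin-watered and water-grown bio4-1 excludes a return to the wild type level, but all 6 arrays lay within 0.58 of their highest value, where a partial fall could be hidden. A stretch of chromosome 4 from another parent also stays open, because 3% of the 100 nearest represented genes separated mutant from wild type arrays without overlap, against 2.7% of all genes and a 95th percentile of 6% over other windows. Another effect of the mutant's genotype was not tested.

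Biotin-watered bio4-1 and wild type differed at 573 genes on arrays 2 and 3. RNA shortened at the 5' end is argued against by overlapping arrays of the 2 groups in the mean 3' minus 5' difference, with a gap of −0.112. Another time of day at harvest stays open, since the clock and light list had a mean absolute difference of 0.512, at percentile 98.6 of random lists. A response to biotin watering that holds on all arrays also stays open: 55.8% of the called genes had the same direction on the arrays numbered 1, against 51.9% of uncalled genes, but 1 array of each group, from a set that stood apart, cannot decide it. An effect of genotype or watering on part of the arrays was not tested. The mean 3' minus 5' difference did separate water-grown bio4-1 on arrays 2 and 3 (1.39 and 1.33) from the others. Wild type had 1.29 and 1.17 there, and biotin-watered bio4-1 had 1.28 and 1.17. In the comparisons with water-grown bio4-1, RNA shortened at the 5' end is therefore not argued against.

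The 6 arrays of 2 groups can be split in 10 ways, too few for a share under 0.05. At least as many changed genes were found in 1 split for bio4-1 minus wild type (5 genes; highest other split 0), in 10 for biotin-watered minus water-grown bio4-1 (0 genes; highest other 0) and in 1 for biotin-watered bio4-1 minus wild type (1 gene; highest other 0).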

How the results depend on the processing

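Leaving out the arrays numbered 1, alone or with a replicate block, the batch of these arrays as a block, and the repeats on arrays 2 and 3 were chosen after the data were seen; the other alternatives were fixed before. The rise of MSRB9 kept its direction and its call under every alternative, at 8.50 to 9.33 against wild type without biotin and 8.44 to 9.32 with it. Over all alternatives, single genes kept direction and side of the threshold in 1967 cases and were newly called in 211. They were no longer called in 47 and turned direction in 43. For lists these were 214, 8, 54 and 18. Many of the genes were named because they were called on arrays 2 and 3. The new calls without the arrays numbered 1, 67 alone and 71 with the replicate block, therefore follow largely from that choice. Array weights gave another 58. Most kept cases were genes not called on 9 arrays that stayed uncalled, so the tally does not measure robustness. The immune and salicylic acid lists lost their call with both other list tests, camera with an estimated correlation and fry. They kept it under the remaining alternatives, all of which used camera at the preset correlation of 0.01. The estimated correlations of their members on 9 arrays were 0.27 and 0.73, far above the preset value, so these kept calls are not evidence of robustness. Signal over background limits dim genes: 11895 of 22746 probe sets passed a level of log2 6 on 3 arrays.

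In the comparisons of bio4-1 minus wild type, biotin-watered minus water-grown bio4-1, and biotin-watered bio4-1 minus wild type, 5, 0 and 1 genes were called on 9 arrays. The first count was 3 with the filter at log2 6, 2 with only the 2 groups compared and 1 at an adjusted p under 0.01. Array weights gave 512, 423 and 1646 genes, with 109 changed back and 274 still changed. Without the arrays numbered 1 these were 453, 366, 573, 115 and 178, and with the batch of these arrays as a block 33, 7 and 1, with 7 changed back. Leaving out 1 array at a time gave 1 to 5, 0 to 1 and 1 to 3 genes, with 0 to 1 changed back. Median centring on arrays 2 and 3 gave 265 higher and 319 lower genes in the first comparison, against 254 and 199, and 316 and 209 in the second, against 165 and 201. The cause of these changes was not tested, except that the filter, the stricter threshold and left-out arrays leave fewer probe sets, calls or samples.

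The labels give the groups the same replicate numbers, and the numbers were not taken as pairs. Deviations of same-numbered samples from their group means correlated at −0.03 to 0.83, and 6 of 9 correlated best with their own number. These means include the arrays numbered 1, whose shift enters the deviations of the other arrays. The check therefore cannot decide whether the numbers pair the samples. With the replicate block, 6, 0 and 1 genes were called, 3 of the 6 shared with the fit without it (AT4G12500 and AT2G15760 had adjusted p of 0.0588), and as a random effect the block gave 17 in the first comparison. With the replicate block, the planned abscisic acid list in bio4-1 minus wild type (adjusted p = 0.144) and the glycosyltransferase list (0.0512) were not called. Without the arrays numbered 1, the replicate block gave 712, 644 and 749, with 249 changed back and 279 still changed.

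These values turned direction, and the cause was not tested. In bio4-1 minus wild type, AT3G08030 went from 0.02 to −0.0203 with quantile normalization, −0.0099 with median centring, −1.60 with array weights and −1.73 without the arrays numbered 1, with or without the block. The photosynthesis list went from 0.02 to −0.0139 with centring, −0.14 with weights and −0.15 without those arrays; LTI30 from −0.51 to 0.62 with weights and 0.64 without those arrays, where HIS1-3 went from −1.28 to 0.14. In biotin-watered minus water-grown bio4-1, array weights gave −0.19 for HIS1-3, −0.64 for PUB19, −0.40 for UGT72B3 and −0.26 for the flavonoid list, against 0.91, 0.55, 0.40 and 0.72. Without the arrays numbered 1 these were −0.54, −0.68, −0.39 and −0.61, and SAG101 went from −0.35 to 0.0365. Centring gave 0.0105 for the glycosyltransferase list and for UGT76E11 and 0.047 for the autophagy list, which had 0.0023 with the 30th percentile filter.

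Leaving out 1 array at a time turned some directions. In bio4-1 minus wild type the values ran from −2.64 to 0.31 for AT1G49500, −1.56 to 0.88 for AT3G08030, −0.0518 to 0.23 for MCCA, −1.15 to 0.15 for LTI30 and −0.18 to 0.0546 for the photosynthesis list. In biotin-watered minus water-grown bio4-1 they ran from −0.36 to 2.04 for BZIP61, −0.16 to 1.59 for HIS1-3, −0.96 to 1.32 for PUB19, −0.52 to 1.00 for XTH16, −0.25 to 0.78 for UGT72B3, −1.70 to 0.0456 for UGT73D1 and −0.45 to 0.16 for UGT76E11. They ran from −0.11 to 0.0144 for the glycosyltransferase list, −0.23 to 0.12 for the autophagy list and −0.17 to 1.34 for the flavonoid list.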

Other observations

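In the fit on arrays 2 and 3, added after the data were seen, 4 further gene lists passed by camera that did not pass on all 9 arrays. In bio4-1 minus wild type, 27 nuclear-encoded photosynthesis genes had a median difference of −0.15 (camera adjusted p = 0.0418, or 0.765 with an estimated correlation), and the median on the arrays numbered 1 was 0.14. In biotin-watered minus water-grown bio4-1, 8 flavonoid and anthocyanin genes had a median of −0.61 (adjusted p = 0.0284, or 0.680 with an estimated correlation) on arrays 2 and 3 and of 3.32 on the arrays numbered 1. No member of the 4 lists was called over all genes. In the comparison of biotin-watered with water-grown bio4-1, 14 genes of autophagy and vacuolar processing enzymes had a median of −0.12 (adjusted p = 0.028, or 0.680 with an estimated correlation), against 0.25 on the arrays numbered 1, and 13 pollen and flower genes one of 0.16 (adjusted p = 0.0228, or 0.464 with an estimated correlation), against −0.0028 on the arrays numbered 1. With the arrays numbered 1 against the others as a block on all 9 arrays, the adjusted p of the 4 lists, in the order named, was 0.996, 0.248, 0.663 and 0.12. By fry, 6 root genes, a list for another cell type, passed in biotin-watered minus water-grown bio4-1 on arrays 2 and 3 (median 0.13, 5 of 6 higher; fry adjusted p = 0.0205, camera adjusted p = 0.354), with none called over all genes and a median of −0.02 on the arrays numbered 1.

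The 2 probe sets without a gene name past the threshold in bio4-1 minus wild type lay between the other groups in biotin-watered plants. The lower one had 5.89, 6.01 and 6.20 in wild type, 4.56, 4.42 and 4.05 in bio4-1 and 5.49, 5.45 and 5.43 with biotin. The higher one had 6.01, 6.09 and 6.27, then 7.25, 7.29 and 7.11, then 6.55, 6.49 and 6.50. In biotin-watered minus water-grown bio4-1 they differed by 1.11 and −0.70, with a limma adjusted p of 0.184 for both.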
